A study of Saccharomyces cerevisiae with 16 samples.

How the data were processed

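RNA levels were measured on Agilent dual-colour yeast expression arrays in 16 samples of Saccharomyces cerevisiae, 8 from a wild-type strain (WT) and 8 from a strain that the labels call PHO84c. Per the labels, this strain carries abundant high-affinity phosphate transporter. Per the labels' protocols, cells grew in synthetic complete medium to an optical density of 0.5, were washed and were diluted to 0.05 in the same medium with 0.5 mM phosphate. Cells were harvested at 0, 1, 5, 8 and 23 h. A treatment tag gives the concentration as 0.5 M, against 0.5 mM in the protocol and 500 µM in the sample titles. The tag was taken as a slip, since 2 other fields agree on the lower value.

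Per the labels' protocols, total RNA was purified with an Epicentre MasterPure kit, amplified and labelled with Agilent's Low Input Quick Amp kit, and array images were read with SpotReader. Each sample names 2 scans. How these were merged, the background correction and the normalization are not given in the sources used here. The deposited values were taken as log2 ratios, and 3 properties of that scale were inferred from the values because the labels do not state them. These are the base of the logarithm, the reference and the centring. The values of each pair of 0 h samples of the same strain and dye averaged 1.00 on the linear scale (1.00175 and 1.00394 in WT, 1.0016 and 1.00257 in PHO84c for Cy3 and Cy5). Within a tolerance of 0.05, 97.8% to 99.97% of the probes had a pair mean of 1. Each sample thus appears to be expressed relative to the 0 h pair of its own strain and dye. That the later samples, all Cy3, are relative to the Cy3 pair is assumed. Sample means lay between -0.000524 and 0.00979. Sample medians lay between -0.00463 and 0.0212, except at 23 h (-0.20 in WT and -0.19 in PHO84c).

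Each strain had 4 samples at 0 h, which used both channels of 2 arrays, and 1 Cy3 sample at each later time. The number of arrays limits the precision, and the ratios carry no signal level, so that probes near background could not be told from bright ones. No label says that the 0 h samples came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical, and each lone later sample was assumed to vary like them.

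The table held 6255 probes, and 6125 to 6231 had a value in a sample. A listed gene name was given for 1608 probes (1607 distinct names), and the other 4647 are unnamed here. All 1607 names were found among the symbols and synonyms of the R64 reference table, which served for names alone. A pair of probes listed as FDH2 was averaged, which left 6254 features. There were 0 columns of other series.

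Changes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the deposited log2 values of all 16 samples, with a mean per strain and time point and the array as a random block (correlation 0.761). A call needed a Benjamini-Hochberg adjusted p under 0.05, over all probes tested in that comparison, and a change of at least 2-fold. The planned design had a dye term common to both strains. Because values are relative to the pair of the same strain and dye, a dye term per strain was used in its place, with 4 residual degrees of freedom, and the planned term was run as an alternative. The strain difference at a time was the PHO84c change minus the WT change. The difference over the 4 later times was fitted to the 8 later samples with time as a block. There each later sample was set against the mean of all its strain's 0 h samples, Cy5 included. The other contrasts took the Cy3 samples at 0 h as reference. The planned comparison of the strains at 0 h was not possible, because each strain's values are relative to its own 0 h samples.

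On simulated data with 5786 probes and known changes of 1.5 on the log2 scale, 97.0% to 100% of changed probes were called in WT and 95.5% to 97.0% for the strain difference at a time. For the difference over 4 times, 88.1% were called. Changes of 0.5 lay under the 2-fold limit and were called in 0% to 4.48%. False calls numbered 0 to 5. The simulated noise had the spread of the fit, which comes from the 0 h samples. For the 4 times it had the spread of the residuals of the later samples. Any further variation of the lone later samples was not simulated, so these numbers do not give the false calls among the real ones.

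The comparisons, the 31 gene lists and the rule for named genes were fixed before the data were examined. By that rule the named genes are the listed members of the PHO regulon, the 5 largest called rises and falls per strain and time, the 10 largest called strain differences each way, and up to 4 members per list. Unnamed probes are given by number, at most 2 each way per comparison. The 30 lists with at least 3 listed members were tested among listed probes with camera (preset correlation 0.01), and with an estimated correlation and fry as alternatives. List medians were set against 10000 random lists of the same size. These could not be matched on mean level, because ratios have none. Other alternatives were quantile normalization, median centring, leaving out probes with a missing value, the most variable probe per name, Cy3 samples alone, no array block, the replicate number as a block, leaving out each 0 h replicate, a trended and robust spread, the fold limit alone, leaving out each later time and, for the difference over the 4 times, a contrast in the fit of all 16 samples. Correlations expected from shared 0 h samples came from 100 simulations of unchanged samples. Description and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.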

Results

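Expression was followed in WT and PHO84c cells for 23 h after a shift to medium with 500 µM phosphate, an intermediate level by the labels. The series title names the question, which is whether cells with abundant high-affinity phosphate transporters start their phosphate starvation response later. Each strain had 4 samples at 0 h and 1 sample at 1, 5, 8 and 23 h. Between 6125 and 6231 of 6255 probes had a value in a sample. The spread over probes was 0.0772 to 0.142 (SD, log2) in the 8 samples at 0 h, 0.325 to 0.464 in the 6 samples at 1, 5 and 8 h, and 1.54 and 1.68 in the WT and PHO84c samples at 23 h. All log2 changes are relative to the same strain at 0 h and are given with the standard error of the limma fit. Later times had no replicates. Every sample is labelled with 500 µM phosphate, and no culture at another level was sampled beside them. A response to the phosphate level thus cannot be told from growth or time in culture.

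The listed gene names limit what can be said about genes, since 1 gene family whose members usually move together did not do so. Probes listed under cytosolic ribosomal protein names spread over log2 changes of -3.00 to 3.99 in WT at 23 h (SD 1.54, 52 probes with a value in both Cy3 samples at 0 h), against an SD of 1.54 over all probes. The central 95% range of random lists of listed probes was 1.13 to 1.90. In PHO84c the 53 such probes had an SD of 1.67, against 1.69 over all probes and a range of 1.29 to 2.05. In 11 pairs of near-identical ribosomal protein gene copies, the probes differed by a median of 1.32 in WT, against 1.29 for random pairs (central 95% range 0.568 to 2.38). The probes of 2 of the 11 pairs lay on opposite sides of 0 by over 1 each. Those listed as RPL11A and RPL11B changed by -1.39 and 3.99, and those listed as RPL1A and RPL1B by 2.67 and -1.44. The closest pairs were RPS14A and RPS14B (-2.19 and -2.29) and RPS22A and RPS22B (0.67 and 0.53). These copies were chosen after their values were seen. The same ribosomal probes correlated between the strains at 0.958 (Pearson r across 51 probes, which are not independent replicates). Over 30 lists in WT and 29 in PHO84c, SDs at 23 h had median percentiles of 57.2 and 49.3 among random lists. They ranged from low values for general stress (2.5 and 1.2), mitochondrial ribosomal proteins (2.7 and 5) and, in PHO84c, the 3 cell type a probes (36.9 and 0.8) to high ones for the respiratory chain (97.2 and 98.1) and zinc regulon (99.7 and 99.9). A gene name stands here for the probe listed under it, and no statement about the gene's own RNA is made.

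**Figure D1:**
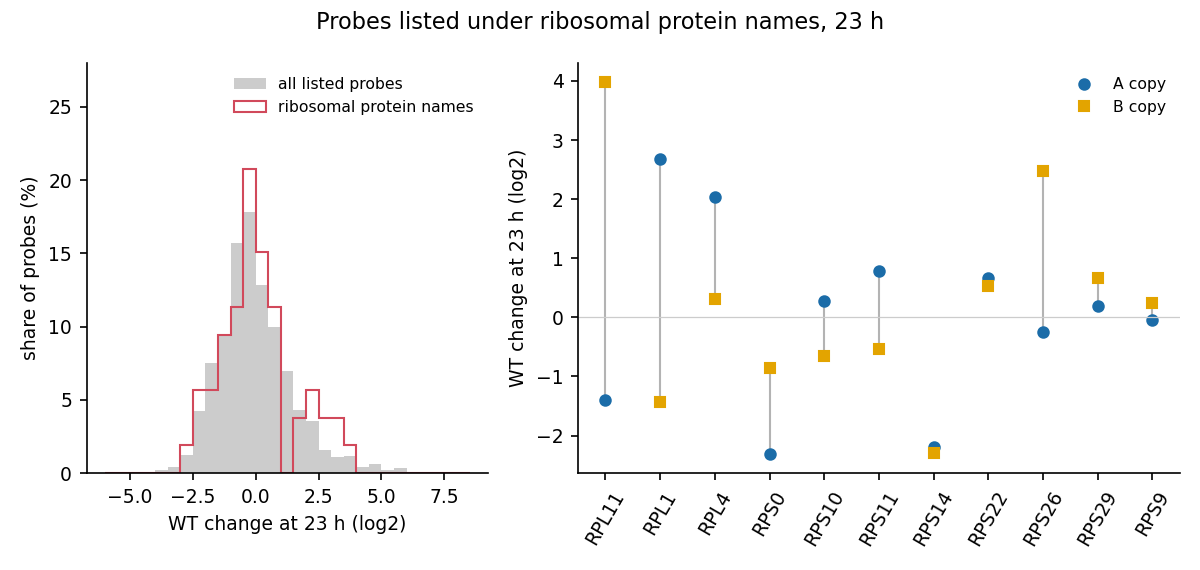
Left, the share of probes (%) by their WT log2 change at 23 h, for probes listed under ribosomal protein names and for all listed probes. Right, the WT log2 change at 23 h of both probes of each listed pair of ribosomal gene copies. The ribosomal probes spread from -3.00 to 3.99, and RPL11A and RPL11B lie on opposite sides of 0.

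In WT, 87 probes were higher and 164 lower at 1 h (of 6197 tested), 57 higher and 82 lower at 5 h (of 6215), and 46 higher and 81 lower at 8 h (of 6230). At 23 h the counts were 1291 higher and 1476 lower of 6198, or 44.6% of the probes. Among listed probes the largest rises at 1 h were MRS4 at 1.69 ± 0.0806, GAS4 at 1.68 ± 0.150, RPD3 at 1.55 and VPS25 at 1.49, and the largest falls were TFA2 at -2.89 ± 0.138, NAT2 at -2.52, CWC15 at -2.44, ARP9 at -2.40 and SSP120 at -2.31. At 5 h CAF17 (3.18 ± 0.217) and HPA3 (2.03) rose most, ahead of GAS4 and VPS25 at 1.79 each, while SSP120 (-2.68), CWC15 (-2.61) and SCM4 (-2.53) fell most. At 8 h GAS4 led the rises at 2.16, followed by MRS4 at 1.39, and SSP120 (-2.67), SCM4 (-2.32) and CWC15 (-2.26) led the falls. Limma's adjusted p for these early probes lay between 1.08e-05 (NAT2 at 1 h) and 0.00331 (VPS25 at 1 h). Changes at 23 h were larger. FET4 rose by 7.77 ± 0.126 (219-fold, limma adjusted p = 3.81e-08), GRH1 by 6.53, KOG1 by 5.97, PAU6 by 5.88 and EPT1 by 5.78. VAM6 changed by -5.49 ± 0.0880, SEF1 by -4.15, GIP1 by -3.92, SEC9 by -3.64 and SEC21 by -3.52. The largest rise of any probe was that of the unnamed probe 2468 (8.37).

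**Figure D2:**
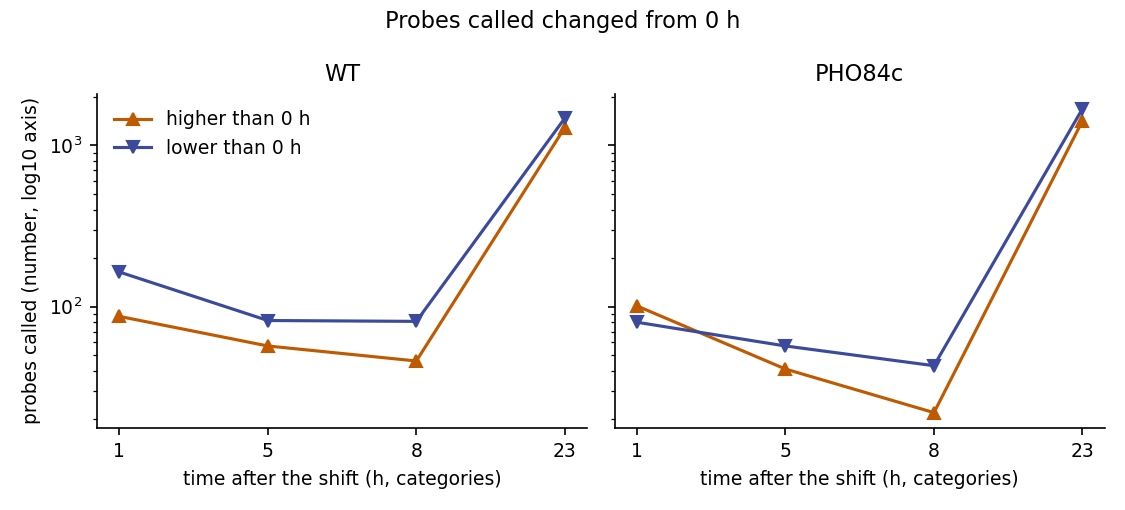
Number of probes (log10 axis) called higher or lower than at 0 h at each later time (h), in WT and PHO84c. Counts stay between 22 and 164 up to 8 h and lie between 1291 and 1689 at 23 h in both strains.

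In PHO84c, 101 probes were higher and 80 lower at 1 h (of 6197), 41 and 57 at 5 h (of 6155), and 22 and 43 at 8 h (of 6124). At 23 h, 1420 were higher and 1689 lower of 6136 (50.7%). NAT3 rose most among listed probes at 1 h (2.28 ± 0.0974), followed by CTF3 (1.46), BTS1 (1.45), GSH1 (1.40) and CCT6 (1.35), and XDJ1 (-2.30 ± 0.109), LAS17 (-2.17), HPA3 (-2.00) and CWC15 (-1.99) fell most. At 5 h CAF17 (2.39), MBP1 (1.95) and UIP4 (1.60) rose and SCM4 (-2.42), SSP120 (-2.07) and CWC15 (-1.91) fell. At 8 h SUL1 (1.51), RRD2 (1.43) and SRD1 (1.11) rose and SCM4 (-2.48), SSP120 (-1.69) and CWC15 (-1.55) fell. Limma's adjusted p for these lay between 6.49e-05 (NAT3) and 0.0125 (SRD1). At 23 h FET4 was again the largest listed rise (7.93 ± 0.126, 244-fold, limma adjusted p = 4.14e-08), ahead of SCT1 (7.02), KOG1 (6.58), SRD1 (6.26) and NIP7 (5.64). AMS1 (-4.56), VAM6 (-4.39), CDC28 (-4.32), PTC1 (-4.23) and SEC9 (-3.93) fell most. The median of all probes had shifted to -0.20 in WT and -0.19 in PHO84c at 23 h. With each sample centred on its median, higher calls there made up 55.7% in WT and 54.0% in PHO84c, against 46.7% and 45.7% as deposited, so which direction held the majority depends on the centring.

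The course in both strains had an early phase and a late one that did not resemble each other. Between strains, the changes correlated at r = 0.522 at 1 h, 0.601 at 5 h, 0.630 at 8 h and 0.934 at 23 h (Spearman's rho 0.450, 0.557, 0.602 and 0.918, across probes, which are not independent replicates). The strains share no 0 h samples, but each time had the same array block number in both strains. An effect of the array block on single probes could therefore also be shared. At 23 h, 1124 probes were higher in both strains and 1238 lower in both, against 294.3 and 400.4 for independent lists. A single probe was called in opposite directions, the unnamed probe 10044 at -1.08 in WT and 1.04 in PHO84c. At 1 h, 18 were higher in both against 1.41 for independent lists, and 52 were lower in both against 2.13. At 8 h the shared calls were 11 higher and 25 lower, against 0.165 and 0.569. Within WT the changes at 1, 5 and 8 h correlated at 0.652 to 0.714 with one another and at -0.188 to -0.0361 with those at 23 h. In PHO84c the same values were 0.490 to 0.727 and -0.161 to -0.127. Unchanged samples set against the same 0 h samples gave 0.333 in WT and 0.327 in PHO84c. Both values are set by the equal spread given to a probe in every simulated sample. The covariances of the early changes (0.106 to 0.122 in WT, 0.0706 to 0.121 in PHO84c) exceeded the simulated 0.00969 and 0.00723. The Cy3 0 h pair was too small to split, and part of the correlations may come from the shared 0 h samples.

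**Figure D3:**
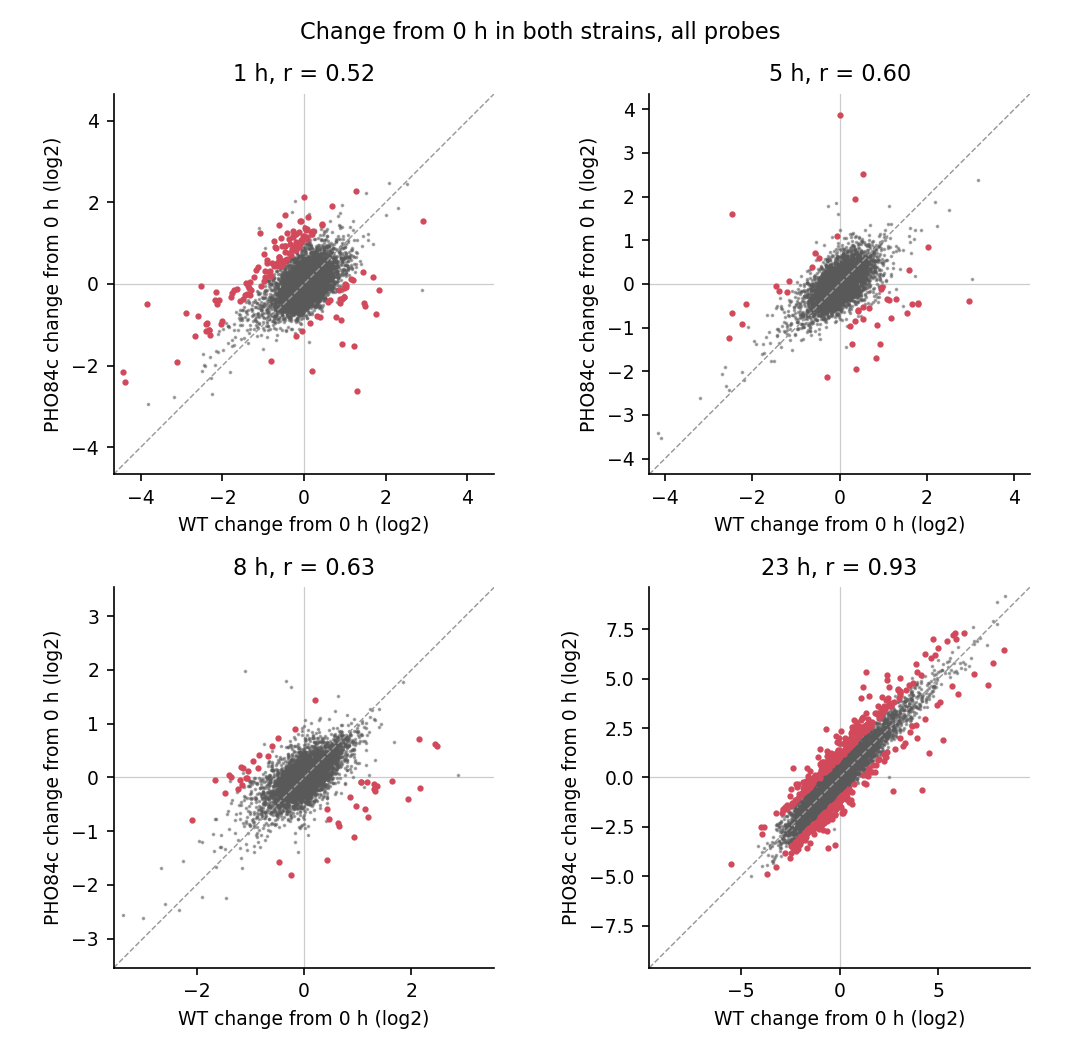
Log2 change from 0 h of every probe in WT (x axis) and PHO84c (y axis) at 1, 5, 8 and 23 h, with Pearson's r across probes, the line of equal change dashed and probes with a called strain difference in red. The strains correlate at 0.52 at 1 h and at 0.93 at 23 h.

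Called in the same direction at 1, 5 and 8 h in both strains were 3 probes upward and 14 downward. Those with a listed name were RPD3 upward and CWC15, RPS22B, SCM4, SSP120 and YHM1 downward, and this group was chosen after its values were seen. RPD3 stayed higher at 23 h (1.30 ± 0.0925 in WT and 2.15 in PHO84c). SCM4, at -2.32 and -2.48 at 8 h, stood at 2.30 and 2.57 at 23 h (SE 0.146). CWC15 moved from -2.26 and -1.55 at 8 h to 1.31 and 1.52 at 23 h (SE 0.0957). The 23 h changes of these 3 probes passed the test, with limma adjusted p of at most 9.28e-06. RPS22B, at -1.67 and -1.37 at 8 h, was called higher at 23 h in PHO84c (1.22 ± 0.0872, limma adjusted p = 6.87e-06) and stayed under 2-fold in WT (0.53, adjusted p = 0.000871). SSP120 and YHM1 were at -0.46 and -0.33 in WT and at 0.25 and 0.49 in PHO84c at 23 h, without a call.

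The PHO regulon, the genes that the transcription factor Pho4 turns on when phosphate is scarce, bears most directly on the question, and 6 of its 19 members had a listed probe. No probe was listed under PHO84, PHO5 or SPL2. VTC4 rose at 23 h alike in both strains, by 1.85 ± 0.190 in WT (limma adjusted p = 5.92e-05) and 1.85 ± 0.190 in PHO84c (adjusted p = 5.39e-05). The strain difference was -0.00 ± 0.268 (adjusted p = 0.992). At 1, 5 and 8 h VTC4 stood between -0.33 and -0.23 in both strains, without a call. PHO81 fell in WT at 1 h (-1.39 ± 0.0998, limma adjusted p = 0.000189) and stood at -0.24 in PHO84c, a difference of 1.15 ± 0.141 (adjusted p = 0.00674). It had no value in PHO84c at 23 h. HOR2 and PHM7 fell in PHO84c at 23 h (-1.32 ± 0.134 and -1.30 ± 0.101, limma adjusted p = 5.02e-05 and 1.14e-05), with WT values of -0.72 and -0.31 that were under 2-fold. Their strain differences of -0.60 and -0.99 were also under 2-fold (adjusted p = 0.0473 and 0.00366). GIT1 differed between the strains at 23 h by -1.20 ± 0.149 (adjusted p = 0.00263), from 0.53 in WT and -0.67 in PHO84c, neither of which reached 2-fold. PHO8 was not called at any time. Adjusted over the list alone, the counts were the same as over all probes at 1 and 23 h, namely 0 higher and 1 lower in WT at 1 h, 1 and 0 in WT at 23 h, and 1 and 2 in PHO84c at 23 h.

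As a list, the PHO regulon did not pass camera in either strain at any time. In WT its median was -0.000151, 0.11, -0.04 and 0.11 at 1, 5, 8 and 23 h, with camera adjusted p of 0.968, 0.802, 0.984 and 0.907. PHO84c gave -0.28, -0.14, 0.02 and -0.67, with 0.982, 0.955, 0.98 and 0.94. The strain difference of the list had medians of -0.16, -0.10, 0.04 and -0.60. The last of these lay at the 2.02 percentile of random lists, and camera gave an adjusted p of 0.961. In WT at 1 h the mean was -0.21 beside a median near 0, and at 5 h in PHO84c the mean was 0.00586 beside a negative median. These medians moved under other settings. At 23 h the WT median was -0.31 without probes with a missing value, 0.31 with median centring and 0.0684 with quantile normalization, which gave -0.12 in PHO84c. Without probes with a missing value, WT stood at 0.17 and 0.33 at 1 and 5 h. Leaving out single 0 h replicates gave 0.0532 to 0.17 in WT at 5 h, -0.10 to 0.00806 in WT at 8 h and -0.000934 to 0.0334 in PHO84c at 8 h.

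Whether the probes that ended high or low at 23 h got there sooner in WT was described over the shared calls. The 1124 probes higher at 23 h in both strains had medians of -0.11 in WT and -0.12 in PHO84c at 1 h, -0.07 and -0.06 at 5 h, and -0.02 and -0.05 at 8 h, before 2.04 and 2.24 at 23 h. At 8 h, 16 of them were called higher and 27 lower in WT, and 8 and 21 in PHO84c. Their median strain difference was 0.05 at 1 h (percentile 100 of 1000 random sets of the same size, 43 called higher and 9 lower in PHO84c), -0.00 at 5 h (26.6) and 0.00 at 8 h (83.6). The 1238 probes lower in both at 23 h had medians of 0.10 in WT and 0.07 in PHO84c at 1 h, 0.05 in each at 5 h, and 0.04 and 0.02 at 8 h. Their median strain difference was -0.08 at 1 h (percentile 0, 18 called higher and 6 lower), -0.02 at 5 h (2.7) and -0.02 at 8 h (7.2). At 1 h the median difference of each set thus lay on the side of its later change in PHO84c, although the PHO84c median of the first set was no higher than that of WT. The calls at 1 h leaned to higher in PHO84c in both sets, as over all probes (115 higher and 33 lower). In the second set that lean ran against its later fall. The random sets were drawn from the same samples, so the percentiles do not measure variation between strains. No time between 8 and 23 h was sampled.

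Strain differences at single probes were tested with 1 array per strain at each later time, so a call does not separate the strain from the array. For these differences, higher or lower in PHO84c refers throughout to the change from 0 h. Levels could not be compared between the strains. The PHO84c change exceeded the WT change at 115 probes and fell short of it at 33 at 1 h (of 6160), at 16 and 26 at 5 h (of 6139), at 21 and 25 at 8 h (of 6116), and at 287 and 203 at 23 h (of 6101). At 1 h NAT2 (2.47 ± 0.130, limma adjusted p = 0.000472), TFA2 (2.18), CIT2 (1.78), SYF1 (1.73), FAA4 (1.69) and URA1 (1.57) were higher in PHO84c. NAT2 stood at -2.52 in WT and -0.05 in PHO84c, and CIT2 at -0.74 and 1.04. Of the 115 probes, 40 were called lower in WT and 36 higher in PHO84c. Lower in PHO84c at 1 h were SIP3 (-2.74 ± 0.168, adjusted p = 0.000596), VPS25 (-2.04), GAS4 (-1.52), ARO3 (-1.21), KCC4 (-1.10), CLB4 (-1.08) and ZDS2 (-1.01). At 5 h MBP1 (1.60) and SNQ2 (1.02) were higher, and VPS25 (-2.25), GAS4 (-2.23), PAT1 (-2.20), GCD2 (-2.11) and SIP3 (-1.97) lower. With any single Cy3 0 h replicate left out, the 42 calls at 5 h became 23 and 21 (WT replicates 1 and 2) or 19 and 18 (PHO84c replicates 1 and 2). At 8 h PKH2 (1.43), BET3 (1.37), APG10 (1.25) and RRD2 (1.22) were higher, and GAS4 (-2.36), HPA3 (-1.72), CCT7 (-1.57) and RRM3 (-1.55) lower. The APG10 call was lost when any 0 h replicate was left out.

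At 23 h SCT1 (2.30 ± 0.230, limma adjusted p = 0.0016), PLO1 (2.10), SPC24 (2.01), RTG2 (2.01), SRD1 (1.95), ISA1 (1.92), SBE22 (1.90), LAS1 (1.85), LEU1 (1.80) and ARO1 (1.75) were higher in PHO84c. SCT1 had risen in both strains, by 4.71 in WT and 7.02 in PHO84c, whereas SPC24 stood at -0.01 in WT and 2.00 in PHO84c. GAS4 showed the largest listed difference of any time, at -4.78 ± 0.212 (limma adjusted p = 0.000146), with 4.16 in WT and -0.63 in PHO84c. INP51 followed at -3.34 (5.24 in WT, 1.90 in PHO84c), then MNN10 (-1.97), PAT1 (-1.90), NGL1 (-1.73), VPS25 (-1.56), HOM2 (-1.53), SYG1 (-1.53), MMT1 (-1.52) and NDC1 (-1.48). Among unnamed probes, probe 14143 differed by 4.01 and probe 10431 by -3.39.

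GAS4 was the only probe whose strain difference was called in the same direction at all 4 times (-1.52, -2.23, -2.36 and -4.78). In WT it rose by 1.68, 1.79, 2.16 and 4.16, and in PHO84c it stood at 0.16, -0.44, -0.20 and -0.63. No probe was called higher in PHO84c at all 4 times. Tested over the 4 later times together, 8 probes were higher and 5 lower in PHO84c of 6222, and 978 had an unadjusted p under 0.05. KCC4 was the only one with a listed name (-1.06 ± 0.124, limma adjusted p = 0.03), and it was lower in PHO84c at 4 of 4 times (-1.10, -0.97, -1.02 and -1.11). The count of 13 fell to 2, 1 and 2 without the 1, 5 or 8 h samples and rose to 29 without those at 23 h. Without 1, 5 or 8 h the KCC4 call was lost. The largest differences were those of the unnamed probes 15377 (2.63 ± 0.360) and 6436 (-2.35 ± 0.142). This test leaves out the error of the 0 h samples, which all later values of a strain share. With the 0 h samples in the fit, an alternative added after the results were seen, 6 of the 13 probes were called and 27 of 5934 in all. KCC4 was called (-1.05 ± 0.101, limma adjusted p = 0.00498), and probe 6436, with an SE of 2.09, was not (adjusted p = 0.442).

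**Figure D4:**
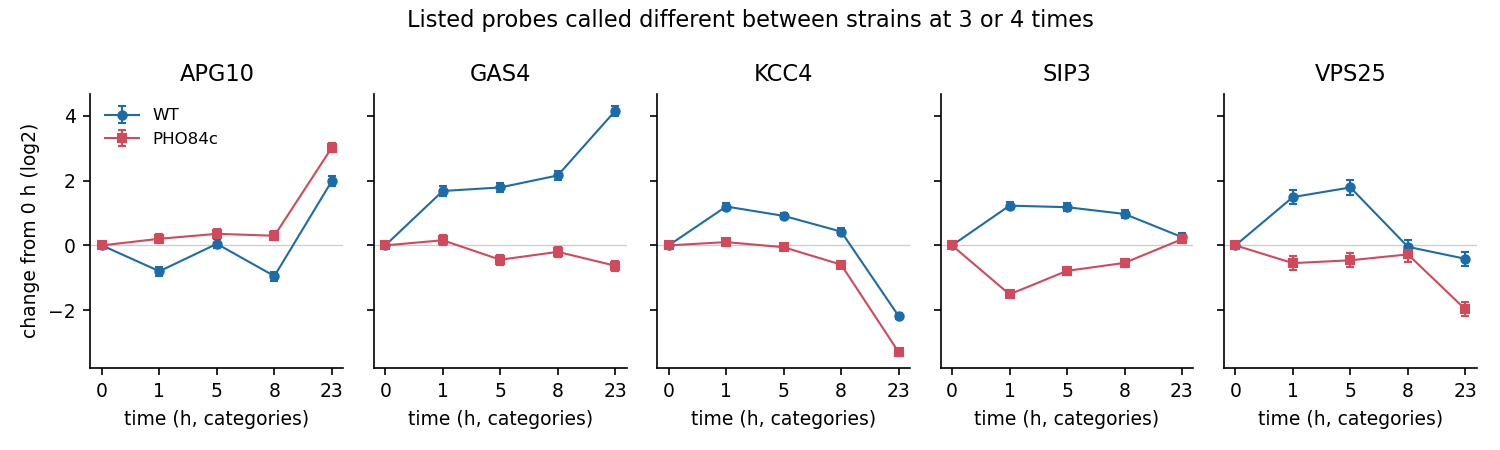
Log2 change from 0 h (± SE of the limma fit) at 1, 5, 8 and 23 h in WT and PHO84c for the 5 listed probes whose strain difference was called at 3 or 4 times. GAS4 reaches 4.16 in WT and -0.63 in PHO84c at 23 h.

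Among the 30 gene lists tested in 360 comparisons, camera called 2, both for probes listed under autophagy names at 23 h. The adjustment was made over the lists within a strain and time, not over all 360. Of the 360, 12 had an unadjusted camera p under 0.05, so the 2 calls are not clearly set apart from chance. In WT its 5 probes had a median of 0.87, with 2 called higher (camera adjusted p = 0.0256, adjusted p = 0.961 with an estimated correlation). In PHO84c the median was 1.35, with 3 called higher (camera adjusted p = 0.0473, adjusted p = 0.983 with an estimated correlation). APG1 rose by 4.54 in WT and APG5 by 2.70, while ICY2 and APG7 stood at 0.87 and 0.59, under 2-fold. For the strain difference no list passed, with the smallest camera adjusted p at 0.995, 0.967, 0.99 and 0.961 at 1, 5, 8 and 23 h.

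None of the other lists passed camera at 23 h. Medians are to be read against the all-probe medians of -0.20 and -0.19. The 16 general stress probes had medians of -0.82 in WT (0 higher, 6 lower) and -0.98 in PHO84c (0 and 8), at the 3.35 and 2.75 percentiles of random lists (camera adjusted p = 0.65 and 0.862). Earlier the same list stood the other way with 0 called, at 0.24, 0.05 and 0.14 in WT at 1, 5 and 8 h (percentiles 98.4, 67.8 and 94.6) and 0.16, 0.23 and 0.19 in PHO84c (92.8, 99.1 and 99.3). Its smallest early camera p was 0.00866 (PHO84c at 8 h, adjusted p = 0.26). Other early list medians outside the central 95% of random lists were, in WT, cytosolic ribosomal proteins at 5 h (-0.09), ribosome biogenesis at 5 and 8 h (-0.16 and -0.11) and nitrogen catabolite repression at 8 h (0.26). In PHO84c they were cell type a at 1 and 5 h (0.58 and 0.46), glucose-repressed genes (-0.25) and mitochondrial ribosomal proteins (0.19) at 5 h, G2, M and M/G1 phase at 5 and 8 h (0.24 and 0.20) and nitrogen catabolite repression at 8 h (0.20). For the strain difference they were the iron regulon at 1 h (0.37) and purine synthesis at 5 h (0.41). None of these passed camera. With 30 lists set against random lists in each early comparison, several medians outside that range are due by chance. These medians are thus not set apart from chance. The 5 pheromone response probes had medians of -1.80 and -1.56 (1 higher and 3 lower in each), and SST2 fell in PHO84c by 3.00 and PRM4 by 2.47 while PRM1 rose by 1.65. Glycolysis and fermentation had medians of 1.15 and 1.01 (3 higher and 1 lower of 6 in each), with ADH1 at 4.75, ENO1 at 2.47 and GPM1 at -1.53 in WT. Methionine and sulfate assimilation stood at 0.37 (4 higher, 1 lower of 9) and 0.80 (5 and 2 of 10), with MET17 at 4.56 and MMP1 at -2.62 in PHO84c. The zinc regulon stood at 0.08 and 0.45 (2 higher and 1 lower of 6 in each), with FET4 at 7.77, ZRT3 at 1.31 and ZAP1 at -1.49 in WT. Cytosolic ribosomal proteins stood at -0.13 (10 higher, 11 lower of 53) and -0.15 (12 and 14 of 54), and ribosome biogenesis at -0.05 (7 and 4 of 26) and -0.23 (6 and 5 of 24). Mitochondrial ribosomal proteins gave -0.58 (3 and 5 of 21) and -0.56 (4 and 4 of 21), and the respiratory chain and ATP synthase gave -0.23 (3 and 4 of 12) and -0.27 (3 and 4 of 11). Beta-oxidation gave 0.54 (2 and 0 of 4) and 1.56 (2 and 0 of 3), with POT1 at 2.69 and POX1 at 1.56 in PHO84c. Purine synthesis gave 0.48 (2 and 1 of 5) and 0.84 (2 and 0 of 5), with MTD1 at 3.50, IMD3 at 2.23 and ADE3 at -1.71 in WT. Glucose-repressed genes gave -1.03 and -0.88 (1 and 4 of 8 in each), and hexose transporters -1.22 (1 and 2 of 4) and -0.76 (0 and 2 of 4). Meiosis gave -1.07 and -1.31 (0 and 2 of 4 in each), with SPS1 at -1.66 in PHO84c, and G1 cyclins and S phase gave -0.37 (1 and 3 of 6) and -0.74 (2 and 2 of 6), with POL30 at -2.09 and CLB6 at 1.15 in WT. G2, M and M/G1 phase gave -0.25 and 0.17 (1 and 2 of 11 in each), and phospholipid synthesis 0.64 (4 and 2 of 11) and 0.13 (3 and 2 of 11). Amino acid synthesis gave -0.19 (3 and 1 of 13) and -0.04 (4 and 3 of 13), nitrogen catabolite repression -0.55 (2 and 2 of 10) and -0.10 (2 and 4 of 10), and the iron regulon 0.11 (3 and 1 of 7) and -0.14 (2 and 1 of 7). Ergosterol synthesis gave -0.29 (1 and 1 of 8) and -0.17 (2 and 0 of 8), the proteasome -0.24 (2 and 2 of 11) and -0.10 (3 and 2 of 11), and the TCA cycle 0.09 (1 and 1 of 5) and 0.36 (1 and 0 of 5). Heat shock proteins gave -0.16 (1 and 1 of 4) and -0.42 (1 and 2 of 4), PHO pathway regulators -0.06 (0 and 0 of 7) and 0.19 (1 and 1 of 7), and histones 0.09 and -0.02 (0 and 0 of 4 in each). Strain markers gave 0.74 and -0.00 (1 and 0 of 3 in each), and cell type a gave -0.36 in each strain (0 and 1 of 3 in WT, 0 and 0 in PHO84c at 23 h). The cell type alpha list had 1 listed member and was not tested.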

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

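The tests of explanations in this part, the split of samples and the fit with the 0 h samples were chosen after the results were seen. The strain differences themselves were planned.

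A test of the difference between the strains in the change from 0 h called 148 probes at 1 h, 42 at 5 h, 46 at 8 h and 490 at 23 h, each with 1 array per strain, and 13 probes over the 4 later times. Among listed probes, 5 were picked out because their difference was called at 3 or more times. For GAS4 it was -4.78 at 23 h and called at 4 of 4 times. VPS25 (-1.56 at 23 h), KCC4 (-1.11) and APG10 (1.03) were called at 3 times each, and so was SIP3, whose difference had gone by 23 h (-0.0640). Without any 1 of the 0 h replicates the APG10 call at 8 h was lost, and without some of them those of KCC4 at 8 h and VPS25 at 5 h. Of the 8 ways to exchange strain labels within time points, 1 gave a count as large as the 13 probes over the 4 later times, which was the true assignment. The highest other count was 0 (71 to 405 probes at an unadjusted p under 0.05 in limma, against 978), and 8 splits are too few for a share under 0.05. An error of the 0 h samples, which all later values of a strain share, would also set the true assignment apart. With the 0 h samples in the fit 6 of the 13 were called, and 3 of the 13 had a called neighbouring probe number, against at most 2 in 1000 random sets.

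Probes listed under ribosomal protein names went both ways at 23 h. Measurement noise is argued against by the correlation between the strains over these probes, 0.958. Names listed beside the wrong probes remain a candidate explanation. The SD of these probes stood at the 60.5 percentile of random lists of listed probes in WT, where wrong names would put it. That value restates the wide spread and is no separate support. The 11 pairs of gene copies differed by a median of 1.32 in WT, against 1.29 for random pairs (percentile 52.6). Wrong names would give this too, but the range of random pairs was wide (0.568 to 2.38). A real divergence of the ribosomal protein genes, copies included, was not tested apart from wrong names and stays open. For other lists the doubt is open, with SDs at median percentiles of 57.2 in WT and 49.3 in PHO84c and single lists at both ends.

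Most strain differences at 1 h were higher in PHO84c. An error of the 0 h samples would be carried into every later sample. The median difference of the called probes, in the direction at 1 h, went from 1.24 at 1 h to 0.517 at 5 h and 0.228 at 8 h. At 23 h it was 0.171 (95% interval 0.0793 to 0.289). The 33 lower in PHO84c went more slowly (-1.24, -0.80, -0.64 and -0.02). The called probes were selected for their size at 1 h, so some fall at other times would follow from the selection. In simulated unchanged samples set against the same 0 h samples, strain differences at different times correlated at only 0.338. That value is set by the equal spread given to a probe in every simulated sample. It does not measure the size of an error of the 0 h samples. An error of the 0 h samples, together with noise at 1 h, would thus also give a fall. The fall does not decide, and such an error stays open. In the simulated data, noise with the spread of the 0 h samples gave 5 false calls for the strain difference at 1 h. Larger noise in the 1 h samples was not simulated. A fault of a region of the array is argued against as the whole cause by the neighbouring probe numbers, with a median of 0.0387 (-0.0514 to 0.101), although 19 of the 148 probes had a called neighbour, against 8.04 in random sets. With 1 array per strain at 1 h, a fault of that array and a difference between the strains cannot be told apart. The difference between the strains thus stays open, as a hypothesis.

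The profiles at 1, 5 and 8 h were shared by both strains. A regional fault of the array is argued against by neighbouring probe numbers. They correlated at no more than 0.0669 in the mean early profile, against 0.662 between the strains. An effect of the array block on single probes would escape that test. Each time had the same array block number in both strains, so such an effect cannot be told from time. Measurement error of the 0 h samples, carried into each later value, is argued against by the lowest covariance between early profiles of a strain, 0.0706, against 0.00723 in simulated unchanged samples. A state of the cells at 0 h that differed from all later times, such as that set by the first medium, was not tested and stays open beside a response to the shift.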

How the results depend on the processing

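The dye term per strain was chosen after seeing the data in place of the planned common term, which then became an alternative. The fit over the 4 times with the 0 h samples included was also added after seeing the data, and all other alternatives were planned. Of 359 comparisons of a count or list median with its value under an alternative, 314 stayed within the limit set (1.5 times for counts, 1 SD for medians), 20 moved, 21 were smaller and 4 larger. PHO regulon medians changed sign in WT at 1, 8 and 23 h and in PHO84c at 8 h under some of these, with values given below. Many of the unmoved values were fixed in advance. Leaving out a 0 h replicate of either strain could not change a median of the other. Without a Cy5 replicate of WT the WT medians were unchanged. Choosing the most variable probe per name touched FDH2 alone. The numbers that stayed, also for the single named probes that follow, are thus no measure of stability. Of the values of single named probes, 5221 stayed on their side of the threshold, 253 lost a call and 7 gained one. Quantile normalization by itself took away every call of a named probe at a single time. Many of the 253 losses and of the 21 smaller counts thus came from that 1 setting.

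Quantile normalization gave 0 calls by limma in each of the 12 comparisons at a time (1 to 100 probes at an unadjusted p under 0.05) and 2 over the 4 times. It gives all samples 1 common distribution, which removes the difference in spread between 0 and 23 h. PHO regulon medians were then 0.0684 in WT at 23 h and -0.23, -0.16 and -0.12 in PHO84c at 1, 5 and 23 h. With median centring they were 0.31 in WT and -0.48 in PHO84c at 23 h. Without probes that lack any value, which leaves fewer members, they were 0.17, 0.33 and -0.31 in WT at 1, 5 and 23 h and -0.32 in PHO84c at 1 h. The fold limit alone gave 83 probes for the strain difference at 5 h. Over the 4 times, leaving out 1, 5, 8 or 23 h gave 2, 1, 2 and 29 probes, and the cause was not tested. With the 0 h samples in the fit there were 27, which held 6 of the 13. Among list tests, an estimated correlation called 0 (2 of 348 at an unadjusted p under 0.05) and fry, which asks another question, 104, against 2.

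Leaving out each 0 h replicate in turn gave 18 to 40 calls for the strain difference at 5 h, against 42. The low counts came without the Cy3 replicates 1 and 2, to which later samples are compared. PHO regulon medians ranged from 0.0532 to 0.17 (WT, 5 h), -0.10 to 0.00806 (WT, 8 h), -0.29 to -0.22 (PHO84c, 1 h), -0.14 to -0.11 (5 h), -0.000934 to 0.0334 (8 h) and -0.72 to -0.62 (23 h). Other counts ranged from 130 to 150 (strain difference at 1 h), 31 to 44 (8 h), 479 to 503 (23 h), 2767 to 2783 (WT, 23 h) and 3102 to 3121 (PHO84c, 23 h). APG10 at 8 h lost its call in all of these, and KCC4 at 8 h and VPS25 at 5 h in some. GAS4 and SIP3 lost their calls under quantile normalization alone.

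The replicate numbers were not taken as pairs, since the deviations of same-numbered 0 h samples correlated negatively between strains (-0.238 to -0.153). The sign was the same for every number, so the deviations of the strains were not unrelated, and the cause was not tested. With the replicate block, strain differences numbered 154, 63, 50 and 507 at 1, 5, 8 and 23 h. A common dye term gave 150, 58, 48 and 495, and Cy3 samples alone 161, 48, 52 and 516. The strain comparison at 0 h was not run under any alternative. Signal over background is not known for these ratios, so no limit from it can be given.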

Other observations

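The sets of probes and the comparisons in this part were chosen after the results were seen.

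Probes that fell at 1 h were often high at 23 h. The 164 probes called lower at 1 h in WT had medians of -1.38, -0.81, -0.74 and 1.58 at 1, 5, 8 and 23 h, and 100 of them were called higher and 18 lower at 23 h. The 80 called lower at 1 h in PHO84c had medians of -1.22, -0.95, -0.74 and 2.11, with 56 called higher and 5 lower at 23 h. TFA2 went from -2.89 at 1 h to 2.26 at 23 h in WT and from -0.70 to 3.21 in PHO84c. HLJ1 went from -1.73 to 1.64 and from -1.14 to 2.18. The 87 probes called higher at 1 h in WT moved the other way, from a median of 1.15 to -0.58, with 19 called higher and 37 lower at 23 h. In PHO84c the 101 called higher at 1 h went from 1.20 to -0.20, with 24 called higher and 30 lower. That is near all PHO84c probes at 23 h (median -0.19, 1420 higher and 1689 lower of 6136). These probes thus lost their rise but showed no reversal beyond that of all probes. In WT the values over all probes were -0.20, 1291 higher and 1476 lower of 6198. Other probes kept their direction. GIC2 stood at -1.20, -1.38, -1.40 and -3.03 in WT, and APE2 at -1.76, -1.69, -1.96 and -1.66.

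The probes that differed between the strains at 23 h had little difference before. The 287 that were higher in PHO84c had median differences of 0.09, 0.14 and 0.04 at 1, 5 and 8 h, and at 23 h stood at -0.02 in WT and 1.32 in PHO84c. Some unnamed probes were called in the sample of a single strain. Probe 9920 rose in PHO84c at 5 h by 3.88 and stood at 0.02 in WT (difference 3.86 ± 0.164, limma adjusted p = 0.000323). Probe 9824, which is 96 numbers away, rose in the same sample by 2.52 and stood at 0.54 in WT, and whether the place on the array had a part in this was not tested. Probe 10431 rose in WT by 2.97 at 5 h and stood at -0.40 in PHO84c (difference -3.37 ± 0.319, adjusted p = 0.00768).

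Profiles of different times were also correlated across strains, over probes, which are not independent replicates. WT at 1 h correlated with PHO84c at 5 and 8 h at 0.517 and 0.550, whereas WT at 5 and 8 h correlated with PHO84c at 1 h at 0.397 and 0.372. WT at 5 h with PHO84c at 8 h gave 0.536 and the reverse 0.551. WT at 1, 5 and 8 h correlated with PHO84c at 23 h at -0.267, -0.173 and -0.105, and PHO84c at 1, 5 and 8 h with WT at 23 h at -0.115, -0.105 and -0.0952. These differences were not tested, and each value rests on 1 array per strain.

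In the 0 h samples, probes with neighbouring numbers had similar values. The correlation between probes 1 number apart averaged 0.376 over the 8 samples, and 0.405 at 96 numbers apart, against 0.155 and 0.0722 at 82 and 164. At 1 number apart the 0 h values ran from 0.181 to 0.293 in WT and from 0.356 to 0.687 in PHO84c. In the 8 later samples the values were 0.0673 and 0.0625 at 1 and 96. The later samples had a larger spread over probes (SD 0.325 to 1.68, against 0.0772 to 0.142 at 0 h), which lowers such a correlation. The lower values thus do not show a smaller effect of the place on the array. Called strain differences were also counted beside one another. Of the 148 probes called at 1 h, 19 had another called probe at a neighbouring number, against 8.04 for random sets (at most 22 in 1000). At 5 h the count was 4 of 42 against 0.631 (at most 7), and at 8 h 4 of 46 against 0.721 (at most 6). These 3 counts lay at the 99.5, 99.6 and 99.5 percentiles of random sets. At 23 h the count was 97 of 490 against 84.6 (at most 123, percentile 86.7). Over the 4 times it was 3 of 13 against 0.082 (at most 2), and probe 5185 was among them.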
